A study of Streptomyces coelicolor with 8 samples.

How the data were processed

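The samples are mycelium of Streptomyces coelicolor M145, a plasmid-free laboratory strain, grown on MS solid medium covered with cellophane and collected at 48 hours, per the labels. There were 3 genotypes: wild type (n = 2 arrays), an ohkA mutant (n = 3) and an orrA mutant (n = 3). By the labels' protocols, the mycelium was frozen in liquid nitrogen and ground, RNA was purified on RNeasy columns and checked for integrity on a Bioanalyzer, and Cy3-labelled cRNA was made with Agilent's one-colour low-input kit and hybridised to 1 array per sample. No source used here says that replicates of a genotype are separate cultures, so every p-value below measures only the spread between these samples, which may be technical.

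The scanner tables hold one intensity per spot, written by Agilent Feature Extraction 10.7.1.1, per the file headers. The processed signal used here was already background-subtracted and detrended within each array, per the file headers. The submitters' processing notes name Agilent Feature Extraction 10.7 and limma without giving either step a role. The deposited normalized table and the series matrix hold log2 values of the same arrays by the authors: their columns matched log2 of the processed signal with r of 0.999 or more across spots, their column medians lay between 6.666 and 6.667, and their lower and upper quartiles between 5.194 and 5.197 and between 8.136 and 8.143. The 2 tables differed from each other by at most 5e-09. Columns of equal distribution are what quantile normalization gives, but the method is not named in the sources used here. These tables served only as alternatives, and their 8 columns of detection marks were not used here.

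Each array held 15505 spots, of which 536 were controls, 77 of them negative controls. The 14969 other spots covered 7734 loci, 7235 with 2 spots and 499 with 1. Control spots and the 42 gene spots that the scanner software marked as outliers were left out, and 0 gene spots were saturated. Between 94.4% and 98.4% of the gene spots of an array were well above background, and the 75th percentile of the signal lay between 157 and 259 times the median of that array's negative controls. A locus was kept when one of its probes was well above background on every array of at least one group, which left out 173 loci. A further 22 were left out because they share a probe sequence with another locus, and 1 because all its kept spots were marked as outliers. This left 7538 loci, or 7537 in the comparisons with the orrA mutant. The log2 processed signal was centred on each array's 75th percentile, and the spots of a gene were averaged on the log2 scale. Between the 2 spots of a gene, the median absolute log2 difference was 0.0911 over 6709 genes. Gene names, products and coordinates are those that the authors' table pairs with the loci, on the A3(2) chromosome. The supplied reference list belongs to another assembly, ASM4782426v1, matched 0 of the locus numbers and was not used.

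Genes were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all 8 arrays in a single fit of 3 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Errors printed after ± are standard errors of log2 differences from that fit. A gene well above background on no array of one group has only a bound. Its fold is then written as "at least N-fold", setting the brighter group's mean against a dim-group mean that takes, per array, the higher of the gene's own signal and the lowest signal well above background. No fold is given where neither group was well above background. The number of arrays limits the precision of every value.

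A set of 41 gene lists was fixed before the data were examined, as were the tests, the filters, the alternatives and the rule for naming genes, except where another time of choice is stated. The lists are the clusters for actinorhodin, prodiginine, calcium-dependent antibiotic, coelimycin, spore pigment, isorenieratene, hopanoid, coelichelin, coelibactin and polyunsaturated fatty acid synthase; the gamma-butyrolactone, desferrioxamine, ectoine and SapB genes; terpene odorants; chaplins and rodlins; bld regulators; the bldK permease; whi and sporulation regulators; sporulation-associated structural genes; the division and cell wall cluster; the mre cluster; gas vesicle-like clusters. They further include two-component systems in antibiotic control, pleiotropic antibiotic regulators, phosphate starvation, nitrogen assimilation, chitin and N-acetylglucosamine use, heat shock chaperones, oxidative and thiol stress, the hypoxia and dormancy island, the cell envelope stress operon, the ribosomal protein operon, ATP synthase, NADH dehydrogenase, arginine biosynthesis, sulphate assimilation, zinc starvation, the fatty acid synthase core, and the neighbours of ohkA and of orrA. The 7 isorenieratene genes also lie in the hypoxia island, phoR and phoP are in both the two-component and the phosphate lists, and mtrA and mtrB are in both the two-component list and the neighbours of orrA. The array lacked 2 list members. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 41 lists, again with an estimated correlation, and with limma's fry, which asks whether a list's genes move one way on balance without comparing them with other genes. Runs of at least 5 consecutive measured loci called in one direction were set against 1000 random orders of the same calls.

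The rule named ohkA and orrA, for each comparison the 10 called genes with the highest and the 10 with the lowest change among those whose groups of arrays did not overlap, 17 fixed regulators, up to 4 called members per list, and the first, last and most changed gene of each run. It covered 1654 gene results. Many run genes reversed sign with normexp background correction, and after this was seen the genes followed one by one through the alternatives were limited to 536, with runs of at least 15 genes against wild type and 8 between mutants. The counts over all 1654 are given with the alternatives.

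All arrays came from 1 slide and 1 scan, so neither could be a block. Row 1 of the slide held the 3 arrays labelled ohkA mutant and orrA mutant replicate 1. Row 2 held orrA mutant replicates 2 and 3 and both wild-type arrays. A fit with the slide row as a block and fits within a row were added after seeing the data, and their values are given beside the counts, beside lists where they change a call or move the median by more than 1.5 times, and for some of the genes. The 6 mutant arrays were also grouped by row instead of by label, likewise after seeing the data. Within a row, the labelled ohkA mutant and wild type cannot be compared, and with the block the contrast of the mutants rests on orrA mutant replicate 1 alone. The blocked contrast of the labelled ohkA mutant with wild type also depends on that array, the only orrA array in row 1.

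The other alternatives were quantile normalization, median centring, the 75th percentile over probes detected on all arrays, normexp correction of the mean and background signals with an offset of 50 followed by either scaling, the authors' table, the series matrix, no filter on dim probes, only probes well above background on all arrays, the brightest probe per gene, a fit of the compared groups alone, the replicate number as a block, eBayes with trend and robust, array weights, each array left out, an adjusted p under 0.01, a 2-fold minimum, and runs of at least 4 or 8 genes. The change shared by the mutants was set against 100 simulated draws of unchanged mutants measured against the same 2 wild-type arrays. After seeing the data it was also computed with 1 wild-type array for each mutant, and shared calls were counted in 100 further draws, at the adjusted threshold and with as many genes taken by moderated t in each direction as were called.

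The tests were tried on simulated data of 7536 genes with known changes, built from each gene's mean and residual spread on the real arrays. For log2 changes of 0.5, 1 and 2, the share recovered was 62.7%, 95.5% and 98.5% for the labelled ohkA mutant against wild type, 65.7%, 89.6% and 100% for the orrA mutant against wild type, and 65.7%, 92.5% and 100% for the mutants against each other. False calls were 11 of 182, 7 of 177 and 11 of 183 in these comparisons. A simulated shifted list of 21 genes was called in each, and 0 other lists were. The simulated genes were drawn independently of each other. In the real lists the estimated correlation was 0.911 for actinorhodin, 0.59 for the ribosomal operon and -0.009 for the division and cell wall cluster. The 0 other calls therefore do not show how often real lists are called falsely. No probes of the plasmids SCP1 or SCP2 were identified on the array, so the negative control intended for the absence of these plasmids is not reported here.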

Results

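Transcript levels were measured on 8 one-colour arrays of Streptomyces coelicolor, a soil actinomycete that forms aerial hyphae and spores and makes several coloured or antibiotic compounds. Mycelium of the wild-type strain M145 (n = 2), of an ohkA mutant (n = 3) and of an orrA mutant (n = 3) had grown on solid medium for 48 hours. ohkA (SCO1596) is annotated as a sensor histidine kinase gene and orrA (SCO3008) as a response regulator gene. A two-component system joins a kinase that senses a signal to a regulator that acts on transcription. The series title gives the question as the genome-wide transcription of both mutants compared with M145. The 75th percentile of the signal lay between 218 and 307 over the arrays. Across genes, which are not independent replicates, r was 0.991 between the wild-type arrays, 0.996 to 0.997 within the ohkA group and 0.995 to 0.997 within the orrA group. It was 0.846 to 0.867 between the labelled ohkA mutant and wild type, 0.816 to 0.834 between the orrA mutant and wild type, and 0.979 to 0.984 between the mutants.

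The deleted genes were read first. Signal at the orrA probe was 1035 to 1524 over the 4 wild-type spots. In the arrays labelled orrA mutant it was 1.23 to 2.73, with 0 of 6 spots well above background and 1 of 6 above the 95th percentile of the negative controls. In the arrays labelled ohkA mutant it was 2.21 to 4.24, with 0 of 6 spots well above background and 6 of 6 above that 95th percentile. orrA was at least 299.9-fold lower than wild type in the arrays labelled ohkA mutant (limma adjusted p = 4.63e-08) and at least 229.5-fold lower in the orrA mutant (limma adjusted p = 1.71e-08). Signal at the ohkA probe was 134 to 172 in wild type, 148 to 190 in the arrays labelled ohkA mutant and 176 to 201 in the orrA mutant, well above background on every spot. The log2 difference of ohkA from wild type was -0.08 ± 0.07 in the arrays labelled ohkA mutant (limma adjusted p = 0.306) and 0.03 ± 0.07 in the orrA mutant (limma adjusted p = 0.739). The ohkA probe thus did not bear out the label. ohkA lies at 1708109 to 1709248 and orrA at 3281872 to 3282630 of the A3(2) chromosome. Which part of either gene was removed is not given in the sources used here, and a probe outside the removed part checks nothing. These 3 arrays are therefore called the labelled ohkA mutant throughout.

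**Figure D1:**
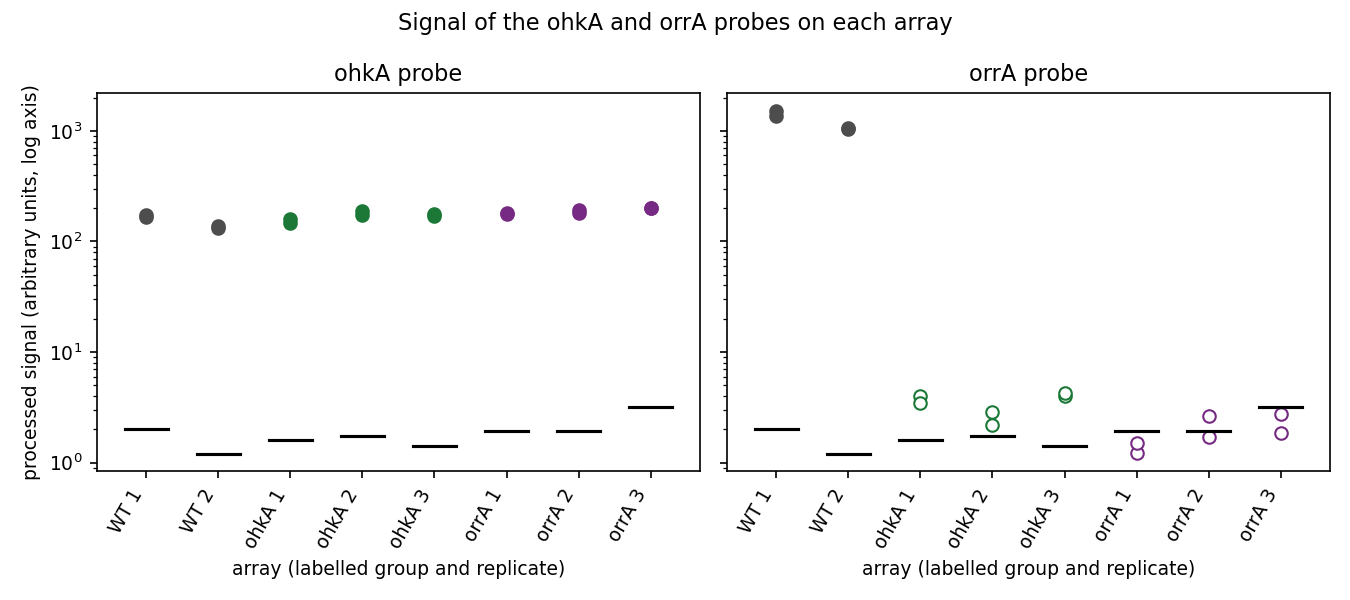
Processed signal (log axis, arbitrary scanner units) at the spots of ohkA and orrA on each array, 1 point per spot, filled where well above background and open where not; grey is wild type, green the labelled ohkA mutant and purple the orrA mutant, and the black bar is the 95th percentile of that array's negative controls. orrA signal was lost in both mutant groups, and ohkA signal in the labelled ohkA mutant (148 to 190) lay near that of wild type (134 to 172).

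The comparison of the labelled ohkA mutant (n = 3) with wild type (n = 2) asks which genes respond to loss of the kinase. Since the ohkA probe does not bear out the label, the directions of this comparison are those of the labelled arrays. actVII and actI-ORF1, which encode enzymes of the actinorhodin polyketide pathway, rose by 8.02 ± 0.18 and 7.96 ± 0.16 on the log2 scale (259.6-fold and 249-fold). rdlA, which encodes a rodlin of the spore surface, fell by 6.66 ± 0.15, and the chaplin genes chpD and chpA fell by 6.40 ± 0.12 and 5.61 ± 0.08. The membrane protein gene SCO7449 fell by 9.15 ± 0.30, and the secreted protein gene SCO5461 fell by 5.68 ± 0.13. The D-lactate dehydrogenase gene dldh and its neighbours SCO3593 and SCO3592 changed by -5.98, -5.84 and -5.79. dldh was well above background on only 2 of the 3 labelled ohkA mutant arrays, so its change lies near the floor. The wild-type standard deviation (n = 2) was 0.503 for actVII, 0.47 for actI-ORF1, 0.785 for SCO7449 and 0.774 for dldh, but 0.009 for rdlA. In the labelled ohkA mutant it was 0.094 for actVII, 0.066 for actI-ORF1 and 0.306 for SCO7449. The errors of these 3 genes, pooled over the groups, are thus too small.

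All 22 actinorhodin genes rose, with a median log2 change of 6.63 (camera adjusted p = 7.55e-13, adjusted p = 0.34 with an estimated correlation). So did all 22 prodiginine genes (median 3.75, camera adjusted p = 1.03e-11, 0.34 with an estimated correlation). Of the 40 genes of the calcium-dependent antibiotic, 35 rose, 2 fell and 3 did not pass, with a median of 4.07 (camera adjusted p = 1.3e-14, 0.251 with an estimated correlation). redU, redG and redN of the prodiginine cluster rose by 6.17, 6.10 and 5.88. In the calcium-dependent antibiotic cluster SCO3244 rose by 7.03 ± 0.14, and fabF3 was at least 85.7-fold higher. The pathway-specific activators actII-ORF4, redD, redZ and cdaR rose by 3.19 ± 0.23, 4.17 ± 0.14, 1.02 ± 0.07 and 2.47 ± 0.08. Their standard deviations were 0.682, 0.308, 0.015 and 0.107 in wild type and 0.032, 0.168, 0.075 and 0.067 in the labelled ohkA mutant. The errors of actII-ORF4 and redD, pooled over the groups, are thus too small. The coelimycin cluster moved less: 12 of 18 genes rose, 2 fell and 4 did not pass (median 0.60, camera adjusted p = 0.0317, 0.64 with an estimated correlation). There SCO6284 rose by 4.96 ± 0.15 while cpkO, which encodes an activator of the cluster, changed by -0.68 ± 0.19. The gamma-butyrolactone genes make and sense a small signalling molecule. Of these, scbB rose by 3.34 ± 0.09 and scbR and scbA fell by 1.48 and 0.92. Their list was not called (median -0.92, mean 0.31, camera pointing down, adjusted p = 0.621, 0.722 with an estimated correlation). Blocked by slide row, the medians of the first 4 clusters were 6.60, 3.86, 4.11 and 0.39. Coelimycin lost its call with that block (adjusted p = 0.2), with normexp background (0.0882, median 0.08 against 0.60) and without wild type replicate 2 (0.054). Its adjusted p ranged from 0.000879 to 0.64 across the alternatives.

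Among other secondary metabolites, 7 of 8 spore pigment genes fell and SCO5317 rose by 3.04 (median -3.03, camera adjusted p = 0.0177, 0.622 with an estimated correlation). All 7 isorenieratene genes fell, the phytoene dehydrogenase gene SCO0186 by 5.06 ± 0.36 (median -3.86, camera adjusted p = 0.00135, 0.436 with an estimated correlation). All 6 genes of the polyunsaturated fatty acid synthase fell (median -2.48, camera adjusted p = 0.00681, 0.34 with an estimated correlation). With only probes well above background on all arrays that median was -1.18 and the call was lost (adjusted p = 0.0894, range 0.000137 to 0.34). Of 11 coelichelin genes, which make and take up a siderophore, 9 fell and 2 did not pass (median -1.27, camera adjusted p = 0.00641, 0.622 with an estimated correlation). Of 13 hopanoid genes, 10 rose and 3 did not pass, or 11 rose when adjusted over the list alone (median 0.62, camera adjusted p = 0.00114, 0.251 with an estimated correlation). The 4 desferrioxamine genes fell, but their list was not called (median -1.20, or -1.11 with bounded members at their bound, camera adjusted p = 0.0992, 0.622 with an estimated correlation). Blocked by slide row their median was -0.55, and SCO2785 (-1.53 to -0.62), SCO2783 (-0.87 to -0.49) and SCO2782 (-0.76 to -0.47) lost their calls (adjusted p = 0.301, 0.296 and 0.298, ranges 0.000148 to 0.301, 0.000637 to 0.296 and 0.00075 to 0.298). Terpene odorants were not called as a list either, of which 2 of 5 rose and 3 fell (median -2.04, camera adjusted p = 0.444, 0.722 with an estimated correlation). Among these SCO7701 fell by 3.68 and the geosmin synthase gene geoA by 2.04. Coelibactin was not called either, with 1 of 9 genes risen and 8 not passed (median 0.19, camera adjusted p = 0.381, 0.683 with an estimated correlation). Ectoine, with 1 of 4 risen, 2 fallen and 1 not passed, was not called (median -0.26, camera adjusted p = 0.557, 0.735 with an estimated correlation).

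All 11 chaplin and rodlin genes fell (median -3.54, camera adjusted p = 4.94e-08, 0.251 with an estimated correlation). So did all 8 whi and sporulation regulators (median -1.73, camera adjusted p = 4.44e-05, 0.251 with an estimated correlation). whiI, wblA and whiH, regulators of sporulation in aerial hyphae, fell by 3.72 ± 0.10, 3.17 ± 0.07 and 3.04 ± 0.07, and whiG, sigF and whiB by 1.58, 1.35 and 0.82. Of 8 bld regulators, which act before aerial growth, 7 fell and 1 did not pass (median -0.97, camera adjusted p = 0.00679, 0.251 with an estimated correlation). bldN and bldM changed by -1.35 ± 0.08 and -1.07. The 5 genes of the bldK permease rose (median 0.62, camera adjusted p = 0.0178, 0.34 with an estimated correlation). Of 14 sporulation-associated structural genes, 10 fell, 2 rose and 2 did not pass (median -0.70, camera adjusted p = 0.00924, 0.34 with an estimated correlation). Among them ssgB, which helps place division septa, fell by 3.38 ± 0.13. The nucleoid protein gene hupS changed by -3.33, and sapA rose by 2.0. In the division and cell wall cluster 12 of 15 fell, 1 rose and 2 did not pass (median -0.72, camera adjusted p = 0.00129, 0.251 with an estimated correlation). In the mre cluster, which shapes the spore wall, 4 of 5 fell and 1 did not pass (median -0.68, camera adjusted p = 0.0467, 0.352 with an estimated correlation). SapB genes were not called, with 2 of 5 risen, 1 fallen and 2 not passed (median 0.07, mean -0.09, camera pointing down, adjusted p = 0.962, 0.977 with an estimated correlation). Gas vesicle-like clusters were not called, with 4 of 19 risen, 9 fallen and 6 not passed (median -0.31, camera adjusted p = 0.224, 0.722 with an estimated correlation). adpA, which encodes a global developmental activator, changed by -0.30 (adjusted p = 0.00422). It lost its call with the slide row as a block (-0.24 ± 0.12, adjusted p = 0.127, range 0.00205 to 0.127 across its alternatives).

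All 21 genes of the ribosomal protein operon fell (median -1.15, camera adjusted p = 6.07e-09, 0.34 with an estimated correlation). ATP synthase genes fell in 8 of 9 cases and 1 did not pass (median -0.85, camera adjusted p = 0.00113, 0.34 with an estimated correlation), and all 14 NADH dehydrogenase genes fell (median -0.64, camera adjusted p = 0.00021, 0.354 with an estimated correlation). Of 10 heat shock chaperone genes 9 fell and 1 did not pass (median -1.12, camera adjusted p = 0.00214, 0.398 with an estimated correlation), with dnaJ changed by -1.66 ± 0.07. Of 15 genes for chitin and N-acetylglucosamine use 13 fell, 1 rose and 1 did not pass (median -0.87, camera adjusted p = 0.00175, 0.251 with an estimated correlation). All 7 arginine biosynthesis genes rose (median 1.58, camera adjusted p = 0.000979, 0.34 with an estimated correlation), argD by 2.54 ± 0.12. Of 10 oxidative and thiol stress genes 8 rose and 2 fell (median 0.73, camera adjusted p = 0.0338, 0.291 with an estimated correlation). The superoxide dismutase gene sodF rose by 2.80 ± 0.15 and the catalase gene catB fell by 2.89 ± 0.30. Blocked by slide row, the medians were -1.13 for the ribosomal operon, -3.83 for chaplins and rodlins, -1.53 for whi regulators and 1.87 for arginine genes. Oxidative stress genes lost their call with the block at about the same median (0.72 against 0.73, adjusted p = 0.053) and without wild type replicate 2 (0.0518), over a range of 4.7e-06 to 0.291. The mre cluster lost its call in 13 of 25 alternatives (adjusted p from 3.52e-05 to 0.352).

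The remaining lists were not called in this comparison. Two-component systems in antibiotic control had 8 of 21 genes risen, 9 fallen and 4 not passed (median -0.06, mean 0.06, camera pointing down, adjusted p = 0.856, 0.897 with an estimated correlation). Among them ecrA1 rose by 1.96 ± 0.15. Pleiotropic antibiotic regulators had 5 of 16 risen, 8 fallen and 3 not passed (median -0.14, mean 0.04, camera pointing down, adjusted p = 0.455, 0.64 with an estimated correlation). afsS, which relays signals to the antibiotic clusters, rose by 3.24 ± 0.11 and atrA by 1.42. Phosphate starvation genes had 4 of 12 risen and 8 not passed (median 0.15, adjusted p = 0.441, 0.759 with an estimated correlation). Nitrogen assimilation genes had 5 of 12 risen, 2 fallen and 5 not passed (median 0.15, adjusted p = 0.326, 0.703 with an estimated correlation). The hypoxia and dormancy island had 7 of 47 risen, 16 fallen and 24 not passed, or 15 fallen when adjusted over the list alone (median -0.12, adjusted p = 0.2, 0.722 with an estimated correlation). It gained a call with normexp background (median -0.18, adjusted p = 0.0176, range 0.0143 to 0.722). In the cell envelope stress operon 1 of 4 genes rose and 3 fell (median -0.28, adjusted p = 0.455, 0.732 with an estimated correlation). Sulphate assimilation had 3 of 10 risen and 7 not passed (median 0.15, adjusted p = 0.455, 0.759 with an estimated correlation). Zinc starvation had 5 of 8 fallen and 3 not passed (median -0.33, adjusted p = 0.0737, 0.572 with an estimated correlation). The fatty acid synthase core had 2 of 4 risen and 2 not passed (median 0.26, adjusted p = 0.441, 0.722 with an estimated correlation). Of the neighbours of ohkA 2 of 9 rose, or 3 when adjusted over the list alone, 4 fell and 3 did not pass (median -0.07, adjusted p = 0.455, 0.64 with an estimated correlation). Those of orrA rose in 4 of 10 cases, fell in 4 and did not pass in 2 (median 0.03, mean -0.03, camera pointing down, adjusted p = 0.856, 0.909 with an estimated correlation). In every other list, the counts adjusted over the list alone equalled those over all genes tested.

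In total, 5039 of 7538 genes were called in the labelled ohkA mutant, 2615 higher and 2424 lower, of which 1650 changed at least 2-fold (814 higher, 836 lower). The wild-type and mutant arrays did not overlap for 5844 genes, 77.5%, where chance gives 20%. With normexp background the called genes split as 1745 higher and 2612 lower, 40.1% higher against 51.9%, and the median change of all genes moved from 0.03 to -0.09. Blocking by slide row left 3848 genes called, 3660 of them among the same calls, and 21 of the called lists stayed called. These groups share no row, so the blocked values depend on orrA mutant replicate 1 alone to link the rows. Of the 41 list medians 31 stayed within 1.5 times. Besides coelimycin and desferrioxamine, the others went from 0.19 to 0.47 for coelibactin, 0.07 to 0.02 for SapB, -0.31 to -0.18 for gas vesicle-like clusters, 0.15 to 0.42 for phosphate, 0.15 to 0.28 for nitrogen, 0.15 to 0.09 for sulphate and 0.03 to 0.29 for the neighbours of orrA. The hypoxia island turned in sign, from -0.12 to 0.14. Camera called 23 of 41 lists, 8 up and 15 down; with an estimated correlation it called 0, with 7 lists under an unadjusted p of 0.05, and limma's fry called 34. Runs of neighbouring genes called in one direction numbered 207, where 1000 random orders gave at most 62 (one-sided permutation p = 0.001, the smallest these orders can give). With the slide row block there were fewer, as given with the alternatives.

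The comparison of the orrA mutant (n = 3) with wild type (n = 2) asks which genes respond to loss of the regulator. actVII rose by 8.47 ± 0.18 and actI-ORF1 by 8.46 ± 0.16, or 354-fold and 352-fold. rdlA fell by 10.55 ± 0.15, or 1503-fold. chpD, chpA and rdlB changed by -8.97 ± 0.12, -6.87 ± 0.08 and -6.24 ± 0.09. SCO7449, SCO5461 and the large membrane protein gene SCO3289 changed by -9.04 ± 0.30, -6.95 ± 0.13 and -6.15 ± 0.07, and dldh was at least 72.5-fold lower. The pooled errors of actVII, actI-ORF1 and SCO7449 are again too small, given their spread in wild type. In the coelimycin cluster SCO6284 rose by 5.18, SCO6276 by 3.93 ± 0.27 and cpkO by 1.68 ± 0.19.

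Each of the 22 actinorhodin genes rose (median 7.09, camera adjusted p = 1.44e-11, 0.392 with an estimated correlation). So did the 22 prodiginine genes (median 3.99, camera adjusted p = 1.27e-10, 0.392 with an estimated correlation) and the 18 coelimycin genes (median 2.05, camera adjusted p = 4.59e-06, 0.392 with an estimated correlation). Of the 40 calcium-dependent antibiotic genes 33 rose, 2 fell and 5 did not pass (median 3.0, camera adjusted p = 1.21e-10, 0.302 with an estimated correlation), and fabF3 there was at least 37.9-fold higher. actII-ORF4, redD, redZ and cdaR rose by 3.50, 4.45, 0.88 and 2.02. scbB rose by 3.42 and scbR and scbA fell by 1.13 and 0.80. The gamma-butyrolactone list was not called (median -0.80, mean 0.50, camera pointing down, adjusted p = 0.694, 0.744 with an estimated correlation). Spore pigment genes fell in 7 of 8 cases and rose in 1 (median -2.89, camera adjusted p = 0.0293, 0.622 with an estimated correlation). Their call was lost with only probes well above background on all arrays (median -2.57, adjusted p = 0.0605, range 0.0018 to 0.622). The 7 isorenieratene genes all fell (median -3.96, camera adjusted p = 0.00233, 0.432 with an estimated correlation). All 6 polyunsaturated fatty acid synthase genes fell (median -2.77, or -2.52 with bounded members at their bound, camera adjusted p = 0.00977, 0.392 with an estimated correlation), which became -1.43 without a call in that setting (adjusted p = 0.0844, range 8.73e-05 to 0.392). Hopanoid genes rose in 11 of 13 cases and 2 did not pass (median 0.65, camera adjusted p = 0.00192, 0.285 with an estimated correlation). Coelichelin, with 9 of 11 fallen and 2 risen, sat at the threshold (median -1.16, camera adjusted p = 0.0499, 0.632 with an estimated correlation). It lost its call in 11 of 26 alternatives, with adjusted p from 0.0139 to 0.632 over all of them. Terpene odorants, with 2 of 5 risen and 3 fallen, were not called (median -2.64, adjusted p = 0.381, 0.674 with an estimated correlation). Neither was desferrioxamine, with 4 of 4 fallen (median -1.39, or -1.12 at the bound, adjusted p = 0.0836, 0.564 with an estimated correlation). Ectoine had 1 of 4 risen and 3 fallen, without a call (median -0.83, adjusted p = 0.256, 0.622 with an estimated correlation). Coelibactin, also not called, had 1 of 9 risen, 7 not passed and 1 fallen, or 0 fallen when adjusted over the list alone (median 0.30, adjusted p = 0.495, 0.703 with an estimated correlation).

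In the orrA mutant all 11 chaplin and rodlin genes fell (median -5.16, camera adjusted p = 3.14e-08, 0.285 with an estimated correlation). The 8 whi and sporulation regulators fell too (median -1.79, camera adjusted p = 0.000111, 0.285 with an estimated correlation). wblA, whiI and whiH fell by 4.56, 3.75 and 3.42, and bldN and bldM by 2.39 and 1.57. Of the bld regulators 6 of 8 fell, 1 rose and 1 did not pass (median -1.29, camera adjusted p = 0.0164, 0.285 with an estimated correlation). adpA did not pass (-0.01, adjusted p = 0.864). The 5 bldK genes rose (median 0.73, camera adjusted p = 0.023, 0.392 with an estimated correlation). In the division and cell wall cluster 12 of 15 fell, 2 rose and 1 did not pass (median -0.52, camera adjusted p = 0.0072, 0.285 with an estimated correlation). The next lists were not called. Sporulation-associated structural genes had 3 of 14 risen, 9 fallen and 2 not passed (median -0.92, adjusted p = 0.0536, 0.432 with an estimated correlation). The mre cluster had 4 of 5 fallen and 1 not passed (median -0.72, adjusted p = 0.0823, 0.432 with an estimated correlation). SapB genes had 2 of 5 risen, 2 not passed and 1 fallen, or 2 fallen when adjusted over the list alone (median -0.09, adjusted p = 0.799, 0.88 with an estimated correlation). Gas vesicle-like clusters had 5 of 19 risen, 8 fallen and 6 not passed (median -0.16, adjusted p = 0.311, 0.744 with an estimated correlation).

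All 21 ribosomal operon genes fell (median -1.55, camera adjusted p = 3.83e-09, 0.392 with an estimated correlation). The 14 NADH dehydrogenase genes fell (median -0.69, camera adjusted p = 0.000305, 0.424 with an estimated correlation), as did 8 of 9 ATP synthase genes with 1 not passed (median -1.18, camera adjusted p = 0.00192, 0.393 with an estimated correlation). Heat shock chaperones fell in 8 of 10 cases, 1 rose and 1 did not pass (median -1.42, camera adjusted p = 0.0072, 0.432 with an estimated correlation). For chitin use 13 of 15 genes fell, 1 rose and 1 did not pass (median -0.98, camera adjusted p = 0.00192, 0.285 with an estimated correlation). The 7 arginine genes rose (median 0.93, camera adjusted p = 0.012, 0.432 with an estimated correlation), as did 8 of 12 nitrogen assimilation genes with 4 not passed (median 0.54, camera adjusted p = 0.0392, 0.432 with an estimated correlation). Among these glnR, which encodes a regulator of nitrogen metabolism, rose by 1.26. Oxidative stress genes rose in 8 of 10 cases and fell in 2 (median 1.0, camera adjusted p = 0.0266, 0.285 with an estimated correlation), with sodF higher by 3.67. The nitrogen call was lost with quantile normalization (adjusted p = 0.0659) and without wild type replicate 1 (0.0638), over a range of 0.000139 to 0.432. With the slide row as a block, and equally within row 2, the medians were 7.08 for actinorhodin, 4.02 for prodiginine, 2.99 for the calcium-dependent antibiotic, 2.06 for coelimycin, -5.20 for chaplins and rodlins, -1.55 for the ribosomal operon and 1.03 for arginine.

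The other lists were not called in the orrA mutant. Two-component systems had 9 of 21 genes risen, 7 fallen and 5 not passed (median 0.05, adjusted p = 0.694, 0.755 with an estimated correlation), with ecrA1 higher by 2.71 and phoR by 1.13. Pleiotropic regulators had 6 of 16 risen, 8 fallen and 2 not passed (median -0.18, mean 0.04, camera pointing down, adjusted p = 0.515, 0.622 with an estimated correlation), with afsS higher by 3.22. Phosphate starvation genes rose in 8 of 12 cases, fell in 1 and did not pass in 3 (median 0.41, adjusted p = 0.0836, 0.622 with an estimated correlation). They gained a call at a smaller median with normexp background and quantile normalization (0.26, adjusted p = 0.0466, range 0.0104 to 0.622). For sulphate assimilation 7 of 10 rose and 3 did not pass (median 0.43, adjusted p = 0.0823, 0.622 with an estimated correlation). In the fatty acid synthase core 4 of 4 rose (median 0.83, adjusted p = 0.0564, 0.471 with an estimated correlation). The hypoxia island had 11 of 47 risen, 16 fallen and 20 not passed, or 10 and 15 adjusted over the list alone (median 0.004, mean -0.83, camera pointing down, adjusted p = 0.356, 0.744 with an estimated correlation), and gained a call with normexp background (median -0.15, adjusted p = 0.0376, range 0.0143 to 0.744). Cell envelope stress had 1 of 4 risen and 3 fallen (median -0.24, adjusted p = 0.575, 0.744 with an estimated correlation). Zinc starvation genes fell in 5 of 8 cases and 3 did not pass (median -0.24, adjusted p = 0.238, 0.622 with an estimated correlation). The neighbours of ohkA rose in 4 of 9 cases and fell in 5 (median -0.25, adjusted p = 0.515, 0.622 with an estimated correlation). The neighbours of orrA rose in 4 of 10 cases, fell in 3 and did not pass in 3 (median 0.19, adjusted p = 0.629, 0.744 with an estimated correlation). For lists without another count, the counts adjusted over the list alone equalled those over all genes.

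**Figure D2:**
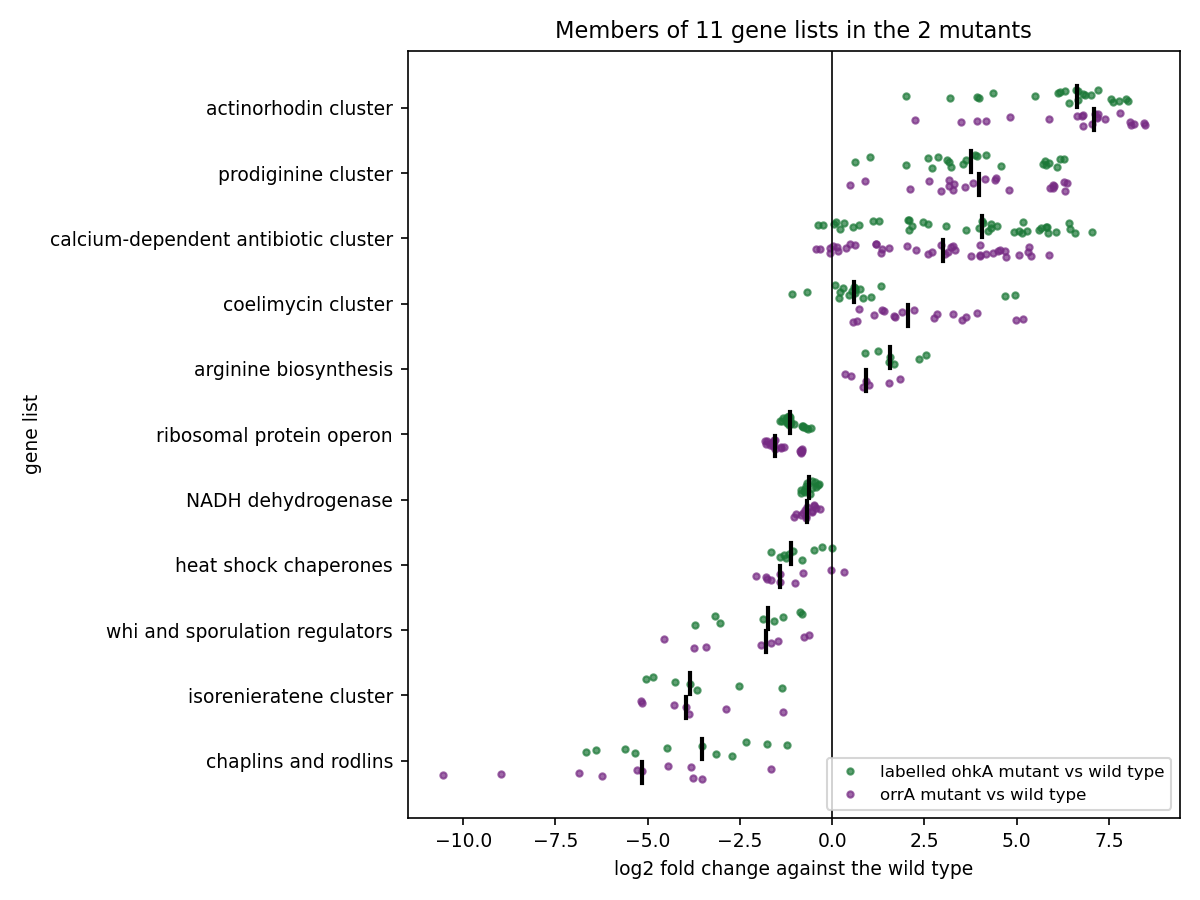
Fitted log2 fold change of each member of 11 gene lists, green for the labelled ohkA mutant against wild type and purple for the orrA mutant against wild type; each point is a gene, members not well above background in a group included at their fitted value, and black bars are medians. Medians of the actinorhodin cluster lie at 6.63 and 7.09 and those of chaplins and rodlins at -3.54 and -5.16.

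In the orrA mutant 5251 of 7537 genes were called, 2744 higher and 2507 lower, and 1983 changed at least 2-fold (957 higher, 1026 lower). The arrays of the groups did not overlap for 5846 genes, 77.6%, where chance gives 20%. With normexp background the split was 1970 higher and 2722 lower, 42% higher against 52.3%, and the median of all genes moved from 0.02 to -0.09. With the slide row as a block, or within row 2, 5141 genes were called, 4982 of them among the same calls, and all 22 lists called stayed called. Of the list medians 38 stayed within 1.5 times. Those of gas vesicle-like clusters, the hypoxia island and the neighbours of orrA went from -0.16 to -0.10, 0.004 to 0.042 and 0.19 to 0.30. Camera called 9 lists up and 13 down; with an estimated correlation it called 0, with 7 lists under an unadjusted p of 0.05, and fry called 38. Runs numbered 221, where random orders gave at most 73 (one-sided permutation p = 0.001, the smallest these orders can give).

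Across 7537 genes, the fold changes of the labelled ohkA mutant and the orrA mutant moved together. Pearson's r was 0.956 and the covariance 1.37, where unchanged mutants simulated against the same 2 wild-type arrays gave a mean r of 0.601 (at most 0.651 in 100 draws) and a mean covariance of 0.00967, a difference of 1.36. The signs were equal for 89.7% of genes, against 70.6% in the simulation. Called genes were higher in both mutants in 2326 cases and lower in both in 2167, where independent lists would share 952 and 806. Unchanged mutants simulated against the same wild-type arrays shared a mean of 0 calls in either direction (at most 1 and 0 in 100 draws). With as many simulated genes taken by rank in each direction as were called, they shared a mean of 1650 and 1473 (at most 1684 and 1517). Only 25 genes were higher in the labelled ohkA mutant and lower in the orrA mutant, and 9 the reverse, where independent lists would give 870 and 883 and the simulated genes taken by rank a mean of 290 and 296. Part of the excess in shared calls may come from the shared controls. With 1 wild-type array as the control of each mutant, so that no control was shared, r was 0.917 and 0.941, the covariance 1.34 and 1.35, and the share of equal signs 84.2% and 86% for the 2 assignments, over 7536 genes.

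**Figure D3:**
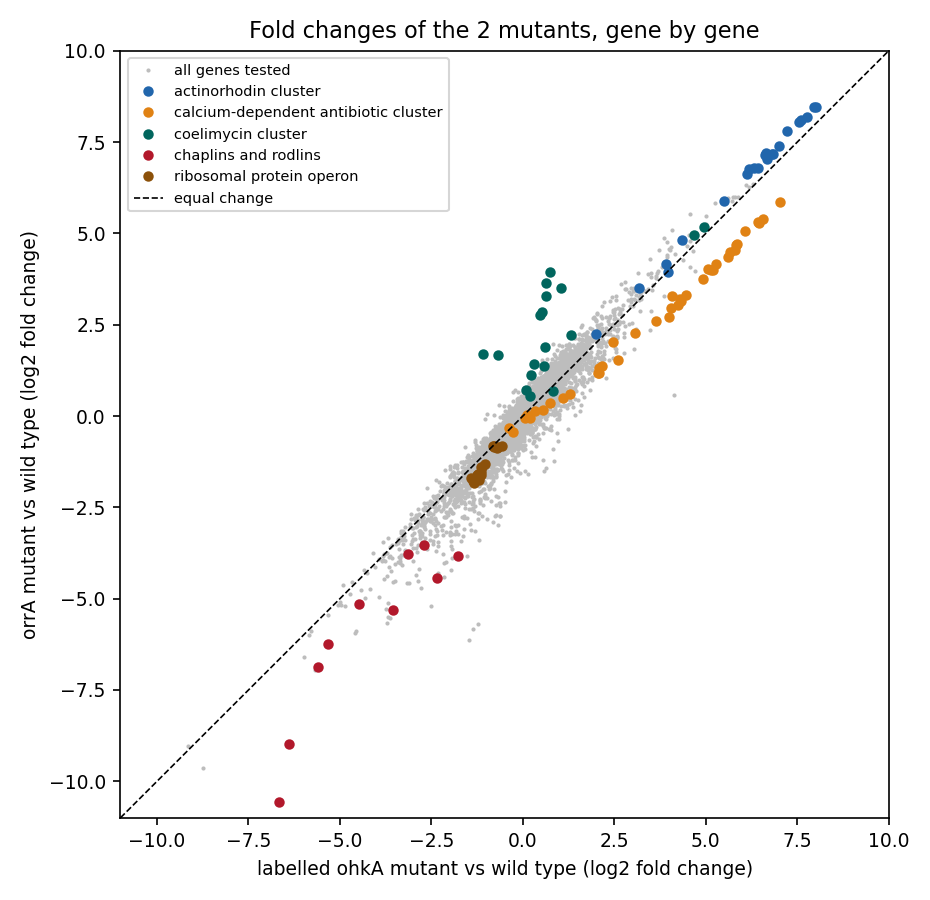
Fitted log2 fold change of each gene in the labelled ohkA mutant against wild type (x) and in the orrA mutant against wild type (y); grey points are all genes, coloured points mark actinorhodin, calcium-dependent antibiotic, coelimycin, chaplin and rodlin, and ribosomal operon genes, and the dashed line is equal change. The points follow the line (r = 0.956), with calcium-dependent antibiotic genes to the right of it and coelimycin genes to the left.

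The comparison of the labelled ohkA mutant (n = 3) with the orrA mutant (n = 3) asks where the mutants differ. Its directions again rest on a label that the ohkA probe does not bear out. SCO3288 and SCO3289, annotated as membrane protein genes, and the neighbouring SCO3290 were higher in the labelled ohkA mutant by 4.45 ± 0.06, 4.68 ± 0.06 and 4.48 ± 0.07 (limma adjusted p = 3.1e-09, 3.1e-09 and 3.85e-09). Against wild type they changed by -1.24, -1.46 and -1.36 in the labelled ohkA mutant and by -5.68, -6.15 and -5.84 in the orrA mutant. rdlA, SCO6666, the calcium-binding protein gene SCO0141, chpD and cvnD7, a gene of a conserved multi-protein signalling operon, were higher by 3.89 ± 0.14, 3.58 ± 0.15, 2.70 ± 0.08, 2.57 ± 0.11 and 2.28 ± 0.12. In the coelimycin cluster genes were lower, SCO6276 by -3.19 ± 0.25, SCO6281 by -3.00 ± 0.21, the receptor gene scbR2 by -2.47 ± 0.25 and cpkO by -2.36 ± 0.17. With the slide row as a block, SCO3289, rdlA, chpD, cvnD7, SCO6276 and cpkO differed by 4.68, 4.17, 2.77, 2.52, -3.27 and -2.55, and by the same values within row 1.

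Coelimycin genes were lower in 15 of 18 cases and 3 did not pass, or 16 lower when adjusted over the list alone (median -1.19, camera adjusted p = 4.46e-11, 0.479 with an estimated correlation). Calcium-dependent antibiotic genes were higher in 34 of 40 cases and 6 did not pass, or 36 higher when adjusted over the list alone (median 1.07, camera adjusted p = 3.35e-22, 0.33 with an estimated correlation). cdaPS1, a peptide synthetase gene, was higher by 1.25 ± 0.07, and the activator gene cdaR by 0.45 (adjusted p = 0.00222, and 0.42 at 0.0595 within row 1, range 0.000411 to 0.0595 across its alternatives). All 11 chaplin and rodlin genes were higher (median 1.25, camera adjusted p = 1.98e-11, 0.33 with an estimated correlation). wblA and bldN were higher by 1.39 ± 0.06 and 1.04 ± 0.07 and bldM, whiH and whiG by 0.50, 0.38 and 0.34. Actinorhodin genes were lower in 8 of 22 cases and 14 did not pass, or 13 lower when adjusted over the list alone (median -0.43, camera adjusted p = 0.000103, 0.681 with an estimated correlation). actII-ORF4 did not pass (-0.31 ± 0.20, limma adjusted p = 0.303). Its standard deviations were 0.032 and 0.077 in the mutants but 0.682 in wild type. The pooled error thus holds wild-type spread and is too large for this contrast. Wild-type spread also entered the errors of other genes of the cluster, such as actIII (0.529, against 0.044 and 0.047 in the mutants). The actinorhodin list lost its call with quantile normalization (median -0.20, camera adjusted p = 0.192) and in the authors' table (-0.26, 0.051), over a range of 3.41e-10 to 0.681. Ribosomal operon genes were higher in 16 of 21 cases and 5 did not pass, or 17 adjusted over the list alone (median 0.36, camera adjusted p = 4.86e-07, 0.519 with an estimated correlation). All 7 arginine genes were higher (median 0.72, camera adjusted p = 5.09e-05, 0.479 with an estimated correlation). Blocked by slide row, the medians were -1.22 for coelimycin, 1.06 for the calcium-dependent antibiotic, 1.33 for chaplins and rodlins, -0.45 for actinorhodin, 0.35 for the ribosomal operon and 0.94 for arginine, and the same within row 1.

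Among smaller lists, the 4 genes of the fatty acid synthase core were lower (median -0.54, camera adjusted p = 0.00449, 0.488 with an estimated correlation). Nitrogen assimilation genes were lower in 8 of 12 cases and 4 did not pass (median -0.34, camera adjusted p = 0.0033, 0.479 with an estimated correlation). They lost their call with quantile normalization (median -0.14, adjusted p = 0.0821) and with normexp background and quantile normalization (-0.11, 0.0569), over a range of 0.000306 to 0.479. The neighbours of orrA were lower in 6 of 10 cases and 4 did not pass (median -0.25, camera adjusted p = 0.0165, 0.479 with an estimated correlation). Oxidative stress genes were lower in 5 of 10 cases and 5 did not pass (median -0.21, camera adjusted p = 0.0363, 0.479 with an estimated correlation). They lost their call in 7 of 26 alternatives, at the smallest median with normexp background and quantile normalization (-0.13, adjusted p = 0.167, range 0.000929 to 0.479). Coelichelin was called lower with 2 of 11 genes lower and 9 not passed (median -0.29, camera adjusted p = 0.0281, 0.761 with an estimated correlation). Its median was -0.49 with the slide row block and within row 1 (adjusted p = 2.5e-05 and 2.97e-05, range 2.5e-05 to 0.761), and -0.19 without a call when orrA mutant replicate 1 was left out (0.185). Sulphate assimilation was called lower with 2 of 10 lower, or 1 adjusted over the list alone, and 8 not passed (median -0.25, camera adjusted p = 0.0281, 0.614 with an estimated correlation). That call too was lost in 7 of 26 alternatives. ATP synthase genes were higher in 6 of 9 cases, or 8 adjusted over the list alone, with 1 lower and 2 not passed (median 0.22, camera adjusted p = 0.0239, 0.548 with an estimated correlation). Terpene odorants were higher in 3 of 5 cases and 2 did not pass (median 0.60, camera adjusted p = 0.0285, 0.519 with an estimated correlation). They lost their call with normexp background and quantile normalization (median 0.31, adjusted p = 0.0704, range 0.00281 to 0.519). Under the slide row block, ATP synthase (median 0.24 against 0.22, adjusted p = 0.109, range 0.00125 to 0.548) and the neighbours of orrA (median -0.19 against -0.25, 0.0792, range 0.00431 to 0.479) lost their calls. So they did within row 1, at the same medians (0.134 and 0.0972).

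The other lists were not called between the mutants in the fit without a block. Prodiginine genes were lower in 2 of 22 cases, or 0 adjusted over the list alone, and 20 did not pass (median -0.18, adjusted p = 0.1, 0.86 with an estimated correlation). Hopanoid genes had 1 of 13 higher, 4 lower and 8 not passed (median -0.16, adjusted p = 0.0835, 0.519 with an estimated correlation). Gamma-butyrolactone genes had 1 of 3 lower and 2 not passed (median -0.12, adjusted p = 0.295, 0.548 with an estimated correlation). Two-component systems had 2 of 21 higher, 7 lower and 12 not passed, or 3 and 8 adjusted over the list alone (median -0.11, adjusted p = 0.118, 0.519 with an estimated correlation). They gained a call with the slide row block and within row 1 (median -0.14 both ways, adjusted p = 0.0235 and 0.0227, range 0.0161 to 0.519). Phosphate starvation had 2 of 12 higher, 5 lower and 5 not passed, or 2 and 6 adjusted over the list alone (median -0.22, adjusted p = 0.118, 0.761 with an estimated correlation). Of the bld regulators 5 of 8 were higher, 2 lower and 1 not passed, or 6 and 2 adjusted over the list alone (median 0.27, adjusted p = 0.0771, 0.479 with an estimated correlation). Of the whi regulators 3 of 8 were higher, 1 lower and 4 not passed (median 0.08, adjusted p = 0.263, 0.681 with an estimated correlation). Ectoine genes had 2 of 4 higher and 2 not passed (median 0.36, adjusted p = 0.0843, 0.519 with an estimated correlation). Chitin use had 4 of 15 higher, 1 lower and 10 not passed (median 0.14, adjusted p = 0.118, 0.519 with an estimated correlation). Heat shock chaperones had 5 of 10 higher, 2 lower and 3 not passed (median 0.27, adjusted p = 0.128, 0.761 with an estimated correlation).

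Further lists were not called between the mutants either. Sporulation-associated structural genes had 2 of 14 higher, 4 lower and 8 not passed (median -0.01, adjusted p = 0.839, 0.916 with an estimated correlation). The division and cell wall cluster had 1 of 15 higher, 5 lower and 9 not passed, or 2 and 6 adjusted over the list alone (median -0.03, adjusted p = 0.283, 0.519 with an estimated correlation). Pleiotropic regulators had 1 of 16 higher, 2 lower and 13 not passed (median 0.02, adjusted p = 0.905, 0.938 with an estimated correlation). The hypoxia island had 2 of 47 higher, 1 lower and 44 not passed, or 0 and 0 adjusted over the list alone (median 0.03, mean 0.02, camera pointing down, adjusted p = 0.841, 0.943 with an estimated correlation). The neighbours of ohkA had 3 of 9 higher, 2 lower and 4 not passed, or 3 and 3 adjusted over the list alone (median 0.09, adjusted p = 0.779, 0.915 with an estimated correlation). Coelibactin had 1 of 9 higher and 8 not passed (median -0.02, mean 0.05, camera pointing up, adjusted p = 0.839, 0.916 with an estimated correlation), and zinc starvation 1 of 8 lower and 7 not passed (median -0.09, adjusted p = 0.283, 0.761 with an estimated correlation). Of the remaining lists limma called no member, over all genes or adjusted over the list alone, and in lists given above without another count both counts were equal. Among these the medians and adjusted p were -0.14 and 0.719 for spore pigment, 0.11 and 0.723 for isorenieratene, 0.14 and 0.811 for desferrioxamine and -0.04 and 0.634 for gas vesicle-like clusters, each with 0.916 at an estimated correlation. They were 0.23 and 0.566 for polyunsaturated fatty acid synthase and -0.06 and 0.566 for bldK, each with 0.86 at an estimated correlation. They were -0.01 and 0.719 for mre and -0.04 and 0.657 for cell envelope stress, each with 0.915 at an estimated correlation, 0.02 and 0.905 for SapB with 0.943, and 0.05 and 0.602 for NADH dehydrogenase with 0.916.

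Between the mutants 2213 of 7537 genes were called, 1104 higher and 1109 lower in the labelled ohkA mutant, and 186 differed at least 2-fold (171 higher, 15 lower). Their arrays did not overlap for 3639 genes, 48.3%, where chance gives 10%. With median centring the split was 935 higher and 1553 lower, 37.6% higher against 49.9%. Blocking by slide row left 1280 called, 1139 of them among the same calls. Within row 1 there were 820, of which 752 were shared. Either way 12 of the 14 called lists stayed called and 1 gained a call, and 22 of 41 list medians stayed within 1.5 times. Besides coelichelin, medians went from -0.18 to -0.06 for prodiginine, 0.11 to 0.21 for isorenieratene, 0.14 to 0.53 for desferrioxamine, 0.23 to 0.40 for polyunsaturated fatty acid synthase, 0.08 to 0.16 for whi regulators and 0.03 to 0.14 for the hypoxia island. Spore pigment (-0.14 to 0.05), coelibactin (-0.02 to 0.17), sporulation-associated structural genes (-0.01 to 0.04) and gas vesicle-like clusters (-0.04 to 0.10) turned in sign. The others that moved were SapB, bldK, mre, pleiotropic regulators, cell envelope stress, NADH dehydrogenase, zinc starvation and the neighbours of ohkA, with medians nearer 0 than 0.1 throughout. Camera called 6 lists higher and 8 lower; with an estimated correlation it called 0, with 4 lists under an unadjusted p of 0.05, and fry called 19. Runs numbered 39, where random orders gave at most 5 (one-sided permutation p = 0.001, the smallest these orders can give). They were fewer with the slide row block and within row 1, as given with the alternatives, and 22 without labelled ohkA mutant replicate 1.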

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

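The tests on the ohkA and orrA probes and those with the slide row were chosen only after the results had been seen; the criteria for the slide row as a block, for other splits of the arrays and for the noise of the shared controls were set before their results were seen. The directions below rest on the label of the ohkA mutant, which its probe does not bear out.

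The difference between the mutants was itself tested with limma and set 3 results apart. Of the genes, 2213 responded differently in the labelled ohkA mutant and the orrA mutant (1104 higher, 1109 lower). Of the lists, 14 did so by camera with a preset correlation, 6 higher and 8 lower, and 0 with an estimated one, where 4 lay under an unadjusted p of 0.05 and fry called 19. In 34 genes the called change against wild type had opposite signs, 25 of them higher in the labelled ohkA mutant. Those with the widest differences were SCO6282, a reductase gene of the coelimycin cluster (-1.08 ± 0.25 in the labelled ohkA mutant and 1.71 ± 0.25 in the orrA mutant), and its neighbour cpkO (-0.68 ± 0.19 and 1.68 ± 0.19). In the other direction stood SCO5191 (0.85 and -1.22), the DNA-binding protein gene SCO5190 (0.63 and -1.41), the ribosome-associated GTPase gene SCO6149 (0.84 and -0.91), SCO6831 (0.97 and -0.68) and the metalloprotease gene SCO5447 (1.23 and -0.35). SCO5191, SCO5190, SCO6149, SCO6831 and SCO5447 were chosen after their values were seen.

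Slide row is a candidate explanation for the genes that differ between the mutants, since row 1 held all arrays of one mutant and only replicate 1 of the other. Against it as the whole cause, grouping the 6 arrays by row instead of by label called 0 genes by limma against 2213 (1264 against 3038 at an unadjusted p under 0.05), and 0 against 1482 to 1790 in the 5 fits that leave out another array than orrA mutant replicate 1. That replicate is the only array that separates row from label (without it both groupings call 1787 genes); its r was 0.9945 to 0.9946 with the orrA arrays of row 2 and 0.979 to 0.983 with its neighbours in row 1, but 1 array excludes nothing and the row stays open. With the row as a block 51.5% of the calls were kept in the same direction, barely past the bound of 50% set beforehand, and 28.7% to 40.9% with another mutant array left out, while signs kept within row 1 were tested on genes picked with the same arrays. The 6 arrays make 10 splits, too few for a share under 0.1: the real split called 2213 genes, as many as 1 of 10 splits including itself, and the highest other split called 0; a difference between the mutants' biology stays open.

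In the arrays labelled ohkA mutant, ohkA signal stood at the wild-type level while orrA signal was lost. Background at the level of the negative controls is excluded at the ohkA spots, as the lowest of them was 8.25 times the brightest negative control spot. Negative controls do not measure signal of other transcripts at this probe, which was not tested. Against RNA of the same cultures as the orrA mutant stand the 2213 genes that differed between the groups and the 820 called within row 1, where SCO3289 differed by 4.68 ± 0.10, but it stays open because the slide row does and row 1 holds 1 orrA array. Other cultures of an orrA deletion stay open, since orrA was not well above background on any spot of either group. Above the 95th percentile of the negative controls lay 6 of 6 spots in the labelled ohkA mutant and 1 of 6 in the orrA mutant. The log2 difference was 0.91 ± 0.25 (limma adjusted p = 0.0277, no fold given). Both go against an equal orrA signal, but signals this near background cannot decide. An ohkA probe outside the deleted part (difference from wild type -0.084) stays open too, as that part is not given in the sources used here. An effect of the labelled genotype on orrA itself stays open, untested.

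The fold changes of the mutants moved together (r = 0.956 across genes). Noise of the 2 shared wild-type arrays is excluded as the whole cause, because the covariance was 141 times that of simulated unchanged mutants. A difference particular to the wild-type cultures themselves stays open, as does a deletion or, with the limit given above, cultures shared by the mutant groups. Like effects of losing ohkA and of losing orrA, the genotypes the design compares, stay open too and were not tested apart from these.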

How the results depend on the processing

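The fits with slide row were added after seeing the data; the other alternatives were set beforehand. A 2-fold minimum left 1650, 1983 and 186 genes called (labelled ohkA mutant against wild type, orrA mutant against wild type, and mutant against mutant), and an adjusted p under 0.01 left 1157 in the last, by construction. Between the mutants the slide row block left 1280 genes, for which the cause was not tested, and row 1 alone, with fewer arrays, left 820. In the other 16 of 17, 17 of 18 and 14 of 18 settings the gene counts moved by less than 1.5 times; single arrays left out, given below, are not among these, and all of these settings spanned 1650 to 5079, 1983 to 5314 and 186 to 2914. Camera's list counts of 23, 22 and 14 went to 0, 0 and 0 with an estimated correlation. That estimate was 0.911 for actinorhodin, 0.932 for spore pigment and 0.59 for the ribosomal operon. It lies above the preset 0.01, which raises p by construction. The division and cell wall cluster, estimated at -0.009 and thus below the preset, lost its call too. In the labelled ohkA mutant its unadjusted camera p went from 0.000346 to 0.0123. Correlation between genes thus does not account for every lost call. With an estimated correlation, camera also uses only the residual degrees of freedom of the 8 arrays, which raises p by construction. Limma's fry, which does not compare with other genes, gave 34, 38 and 19. In the other settings the list counts moved less than that. Runs numbered 207, 221 and 39; by construction a minimum of 4 genes gave 350, 362 and 78 and one of 8 gave 53, 57 and 8. With the slide row block the runs were 124 in the labelled ohkA mutant and 15 between mutants, with row 1 alone 11, and with array weights 61 between mutants; the cause was not tested. The correlation of the mutants' changes was 0.945 with the slide row block and 0.9451 to 0.9564 over 15 settings.

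Named genes reversed only as follows. With normexp background and the 75th percentile SCO7688 went to -0.017 in the labelled ohkA mutant and -0.067 in the orrA mutant and SCO6582 to -0.003 in the labelled ohkA mutant. In the orrA mutant SCO1864, SCO4521, SCO5098 and SCO6300 went to -0.058, -0.059, -0.069 and -0.091. The cause was not tested, though the median of all genes also moved in that setting, from 0.026 to -0.089 and from 0.023 to -0.09. Of all 1654 genes the naming rule covers, 58 reversed there, 3 with the slide row block and 0 in the other settings tried on them. The gamma-butyrolactone list, with medians of -0.919 and -0.802, was called upward by fry (adjusted p = 0.00151 and 0.000248) and not called, pointing down, by camera; the cause was not tested.

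Beyond the changes given with the results, coelichelin, oxidative stress and sulphate assimilation lost their calls between the mutants in 7 of 26 alternatives each (ranges 2.5e-05 to 0.761, 0.000929 to 0.479 and 0.00502 to 0.614). Normexp background gave calls to gas vesicle-like clusters in the labelled ohkA mutant (0.032, range 0.0167 to 0.722), to sulphate assimilation (0.0176, range 0.0104 to 0.622) and the fatty acid synthase core (0.011, range 0.000405 to 0.471) in the orrA mutant, and between the mutants to prodiginine (0.0311, range 0.0261 to 0.86), hopanoid (0.0376, range 0.0104 to 0.519) and heat shock chaperones (0.0376, range 0.034 to 0.761). Sporulation structural genes gained one in 8 of 26 alternatives in the orrA mutant (range 1.75e-05 to 0.432), and bld regulators in 6 of 26 between the mutants (range 0.000565 to 0.479). The cause was not tested. With the slide row block 24 of the 195 named results of the labelled ohkA mutant lost a call, 5 of the 194 of the orrA mutant, and 53 of the 147 between the mutants, or 74 within row 1; some of these named results had no call to lose.

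Single arrays decided some list calls, and the cause was not tested. In the labelled ohkA mutant, without wild type replicate 1 the mre cluster lost its call (0.0758) and the hypoxia island (0.0409) and zinc starvation (0.0444) gained one. Without wild type replicate 2 coelimycin (0.054), mre (0.0518) and oxidative stress (0.0518) lost theirs and desferrioxamine (0.0339) gained one; mre also lost it without labelled ohkA mutant replicate 1 (0.0555) or orrA mutant replicate 3 (0.0515). In the orrA mutant, without wild type replicate 1 coelichelin (0.0928) and nitrogen (0.0638) lost their calls and sulphate (0.0181) gained one. Without wild type replicate 2 desferrioxamine (0.0353), sporulation structural genes (0.0353) and the fatty acid synthase core (0.043) gained one. Coelichelin lost it without labelled ohkA mutant replicate 1 (0.053) or 2 (0.0542) or orrA mutant replicate 2 (0.0664) or 3 (0.0654), and without the last the sporulation genes gained one (0.0498). Between the mutants, without orrA mutant replicate 1 coelichelin (0.185), oxidative stress (0.0902) and sulphate (0.102) lost their calls. Oxidative stress lost it without labelled ohkA mutant replicate 2 (0.0547) and coelichelin without labelled ohkA mutant replicate 3 (0.05), without which phosphate (0.0393) and prodiginine (0.0305) gained one. Prodiginine gained one without labelled ohkA mutant replicate 1 (0.0261), and ectoine without either wild-type array (0.0295).

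Leaving out each array in turn gave 4644 to 5101, 4935 to 5202 and 1482 to 2575 genes, 21 to 24, 21 to 25 and 11 to 15 lists, and correlations of 0.9523 to 0.9586. Runs went over 168 to 210, 185 to 213 and 22 to 48, the last being 22 without labelled ohkA mutant replicate 1, 23 without labelled ohkA mutant replicate 3 and 23 without orrA mutant replicate 2 or 3. An arm left with 1 array is assumed to vary like the other groups.

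The replicate number as a block gave 4661, 4935 and 1632 genes, 22, 22 and 14 lists, and 184, 193 and 25 runs, with a correlation of 0.956. Deviations of same-numbered arrays from their group means had r of -0.243 to 0.043 over 7 pairs, and -0.133 to 0.322 over the 14 others. In groups this small the deviations mirror each other, so the pairs are not independent. These values therefore cannot decide whether equal numbers mark samples handled together. A block for slide or scan was not run, since there was 1 of each. At signals not well above background, 85, 93 and 10 of the called genes have only a bound.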

Other observations

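The rule for runs was set beforehand, and no tests here were chosen after the result was seen; the runs described, from those that no fixed list holds, and their genes were chosen after their values were seen. A stretch of neighbouring genes from SCO4245 onward rose in both mutants, again under a label that the ohkA probe does not bear out. It held 17 genes up to SCO4261 in the labelled ohkA mutant (median log2 change 3.51) and 22 genes up to SCO4266 in the orrA mutant (median 3.32). Its response regulator gene SCO4261 rose by 5.0 ± 0.11 and 5.26 ± 0.11. The 24 genes from SCO0379 to SCO0402, at 393498 to 424406 on the chromosome, rose by a median of 1.31 in the labelled ohkA mutant and 1.23 in the orrA mutant. That run starts with the catalase gene catA and holds the asparagine synthetase gene SCO0386 (1.63 and 1.54). From SCO6427 to SCO6439, 13 genes rose by medians of 3.14 and 3.91, among them the peptide synthase genes SCO6431 (3.73 and 4.56) and SCO6432 (3.14 and 3.91), and 10 of that stretch were lower in the labelled ohkA mutant than in the orrA mutant (median -0.83). The 5 genes from SCO7449 to SCO7453 fell in both (medians -4.73 and -4.87).

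Between the mutants, runs of 7 genes each, from SCO6793 to SCO6799 and from SCO1624 to SCO1630, were higher in the labelled ohkA mutant (medians 1.25 and 1.59). Each holds a conservon, an operon for a membrane kinase with small partner proteins and a GTPase. Against wild type cvnA7 fell by 1.61 in the labelled ohkA mutant and by 2.75 in the orrA mutant, and cvnA9 by 0.63 and 2.46. The cytochrome P450 gene SCO1626 beside it changed by -0.48 and -2.06. A run of 9 genes from SCO6566, which encodes a ROK family protein, to SCO6574 was also higher (median 0.60). There the changes against wild type were upward, by 2.16 and 1.63 for SCO6566.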
